A study of Mus musculus with 4 samples.

How the data were processed

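Single-cell RNA sequencing was done on CD4 T cells of the small intestinal lamina propria, the connective tissue under the gut epithelium, from 4 Rag1-/- recipient mice, which have no T or B cells of their own. Per the labels' protocols, the recipients were irradiated and received 10000000 bone marrow cells, of which 50% came from wild type CD45.1 donors and 50% from Bcl3-/- CD45.2 donors, and were analysed after 16 weeks. Peyer's patches were removed, the tissue was treated with EDTA and digested with collagenase D and DNase I, lymphocytes were enriched on Percoll, and live CD45+CD3+CD4+ cells were sorted. Before sorting, the cells carried 2 barcoded antibodies, against CD45.1 and CD45.2, so that the donor of each cell could be read from the same droplet as its RNA. Libraries were made with the 10x Genomics 3' chemistry, which counts the 3' ends of transcripts.

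The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene or antibody tag and cell barcode, whole numbers with no normalization, per the file headers and labels. They were made with Cell Ranger 6.1.1 on genome build mm10, per the submitters' processing notes; the gene annotation used for counting and any filter after cell calling are not given in the sources used here. Each of the 4 libraries has 31053 genes and 2 antibody tags. Gene positions were taken from GENCODE M21, the annotation of the same build (GRCm38), by Ensembl identifier. At most 33 barcode sequences were shared between any 2 libraries, none with the same UMI total, so each library was counted as its own sample.

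Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial counts, which left 9301, 9244, 3626 and 1415 of the 10011, 10093, 3673 and 1662 barcodes of recipients 1 to 4. Scrublet, run per library in scanpy 1.11.5, marked 29 barcodes (0.123%). This share is too low for the caller to have worked, so doublets were in effect not removed, and cells above 3 times their library's median UMI count were left out as an alternative. The donor was called per library with a mixture of 2 Gaussian components on the log2 ratio of the tags, at a posterior of at least 0.99 and at least 10 tag UMIs. The mixture was fitted by an iterative procedure written for this purpose (scipy 1.17.1). In all 4 libraries the 2 component means lay on opposite sides of 0, the only check made of their separation. The CD45.1 component was wide in recipients 1 and 2 (SD 2.31 and 2.11). There, 79 of 817 and 131 of 978 CD45.1 cells were unassigned under a fixed 4-fold ratio of scaled tags. Doublets of both donors among the CD45.1 cells were not excluded. Cells without a call stayed unassigned and out of comparisons between donors.

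Clusters were made from 2000 variable genes, 30 principal components with recipient means removed, 20 neighbours (scikit-learn 1.9.0) and Leiden clustering at resolution 1.0 (leidenalg 0.10.2). Bcl3, Ptprc, sex-linked genes (here Xist, Tsix and a few genes of the Y chromosome), T and B cell receptor segments, ribosomal, mitochondrial, dissociation, interferon and NF-kB genes were left out of the variable genes. Clusters were named from fixed markers of 17 classes. At least 3 markers of a class, and more for the longest sets, had to be detected in at least 5% of the cluster's cells and 1.5-fold above the other cells. A cluster stayed unnamed when too few markers passed or when classes tied. It also stayed unnamed when none of the markers was among its top 10 genes, or when another class had more markers there. Of 16 clusters, 8 were named as a CD4 class, 1 of 74 cells as myeloid-like, which was left out, and 7 stayed unnamed. This left 23483 cells, of which 1927 were CD45.1, 21219 CD45.2 and 337 unassigned.

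Raw counts were summed per recipient and donor, and per class where a sum had at least 20 cells. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and its default filter on low counts, the recipient as a block, and Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are CD45.2 minus CD45.1 throughout, with standard errors (SE); means are counts scaled to library size (CPM) with the standard deviation (SD) over recipients. Both donors' cells of a recipient come from the same animal, so the recipient pairs them. The correlation of the paired deviations was 0.139, 0.172, -0.000828 and 0.547 in recipients 1 to 4 over 4310 genes. In recipients 1 and 4 the own pair had the highest correlation. The CD45.1 cells of recipient 2 correlated more with the CD45.2 cells of recipient 3 (0.306), and those of recipient 3 with the CD45.2 cells of recipient 2 (0.192). The values thus bear out the pairing in recipients 1 and 4 only. The design asked for 3 recipients per class, which only naive/central-memory-like cells reached; Th1-like, Treg-like, Th17-like and Tfh-like cells were fitted with the 2 recipients that had enough cells, a departure from the plan that leaves 1 residual degree of freedom. A class-matched comparison took equal numbers of cells of both donors per recipient and class, 1927 of each, with each unnamed cluster taken as a class of its own.

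Class shares were tested with the same edgeR test on cell numbers, and donor odds and class odds with exact two-sided sign-flip permutation tests, the class odds after adding 0.5 to each cell number. Of 30 gene lists of T helper programmes, signalling responses and markers of other cell types, those with at least 5 tested members were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists. Shares of cells have exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 counts of the total; both cover counting error only. Shares of barcodes with a UMI were compared after thinning each barcode to 3000 UMIs.

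The designs, classes, lists and most other settings were fixed before the data were examined, as was the rule for named genes. For all CD4 T cells it takes Bcl3, the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 3 and the same direction in every recipient, and up to 3 called members per list. For each class it takes 5 rises, 5 falls and up to 2 members per list. Receptor and immunoglobulin segments, the same sex-linked genes and gene models were left out of the largest changes, while other genes of the X chromosome stayed in. Genes within 10 Mb of Ptprc or Bcl3 are named as such. Gene models and segments were counted but not named, and a few genes that the rule names are not reported here.

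The fits were tested on simulated data, with 200 genes changed in each of 5 draws. At a log2 change of 1 the fit of all CD4 T cells recovered 423 of 485 changed genes, and at a log2 change of 2 it recovered 472 of 473; 9.94% of its calls were false, above the 5% the threshold aims at, and 7.98% to 14.0% over single draws. The draws were raised to 5 after the first one had shown the highest share. The false share was 6.46% for class-matched, 6.06% for naive/central-memory-like and 4.20% for Th1-like cells, and their recovery at a log2 change of 1 was 92.1%, 79.9% and 78.8%. A Th17 list raised in the simulated data was called in 5 of 5 draws in each of these 4 comparisons. Over the 5 draws, 1 other list was called in naive/central-memory-like and 1 in Th1-like cells. In all CD4 T cells and class-matched cells 0 were. Genes were drawn independently and all members raised by a log2 change of 1, so the list test was not tried on correlated genes. A class share raised 4-fold was called in 96% of 100 simulations, with a mean of 0.45 of the other classes called. These simulations used the same mean shares in every recipient and a fixed spread that was not estimated from the data. They therefore do not measure the power of the test on the real shares.

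Other settings fixed in this way were DESeq2 1.42.0, no filter, no block, a fixed 4-fold ratio of scaled tags as donor call, Scrublet calls kept, equal cells of both donors, at least 1000 genes and at most 5% mitochondrial counts, other resolutions (0.6 and 1.5), no removal of recipient means, all variable genes, other windows around Ptprc and Bcl3 (5 and 20 Mb), and each recipient left out in turn. Chosen after seeing the data were the removal of very deep cells, named classes only, sums of at least 10 cells and cluster-matched cells. So were clusters made without the genes called in the class-matched comparison, unnamed clusters kept apart, and the removal of mixed-profile barcodes. The last are groups of a recipient and cluster with at least 50 barcodes of which over 50% hold Igkc; this rule was redefined once after it had first picked out a single cluster. The comparison of gene lists between classes, planned only for the case that the donor could not be read, was not run.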

Results

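CD4 T cells were profiled by droplet single-cell RNA sequencing from the small intestinal lamina propria of 4 mixed bone marrow chimeras, each a Rag1-/- mouse that carried both wild type CD45.1 and Bcl3-/- CD45.2 haematopoietic cells. BCL3 is an atypical IkB protein that binds the p50 and p52 subunits of NF-kB. All 4 recipients form a single group, and the comparison lies inside each animal, between the cells of the 2 donors. The libraries of recipients 1 to 4 held 60347749, 59190104, 41160778 and 8642411 UMIs over 10011, 10093, 3673 and 1662 barcodes, with medians of 5790, 5609, 8584 and 5439 UMIs and 2231, 2125, 2580 and 2160.5 genes per barcode. After filtering, 23483 cells were classified. The summed counts of all CD4 T cells ranged from 287518 UMIs, for the CD45.1 cells of 1 recipient, to 51949529 UMIs, so that the wild type side had the lower precision throughout.

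The targeted gene was examined first, in every recipient. Bcl3 (ENSMUSG00000053175, a protein-coding gene on the minus strand of chromosome 7 from 19808462 to 19822770 in mm10) was higher in the cells labelled Bcl3-/- than in those labelled wild type in all 4 recipients. Its level was 35.1, 27.6, 43.9 and 14.1 CPM in the CD45.1 cells of recipients 1 to 4, and 69.6, 73.7, 113 and 68.1 CPM in their CD45.2 cells. The means were 30.2 ± 12.7 and 81.1 ± 21.4 CPM (SD, n = 4), a log2 fold change of 1.35 (SE 0.18, edgeR adjusted p = 0.0013), from 410 and 11994 UMIs. The part of the gene that the allele lacks is not given in the sources used here, and 3' tags outside that part check nothing, so the counts settle neither the genotype nor which donor is which. Groups are therefore called by their labels, and every direction below rests on those labels.

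**Figure D1:**
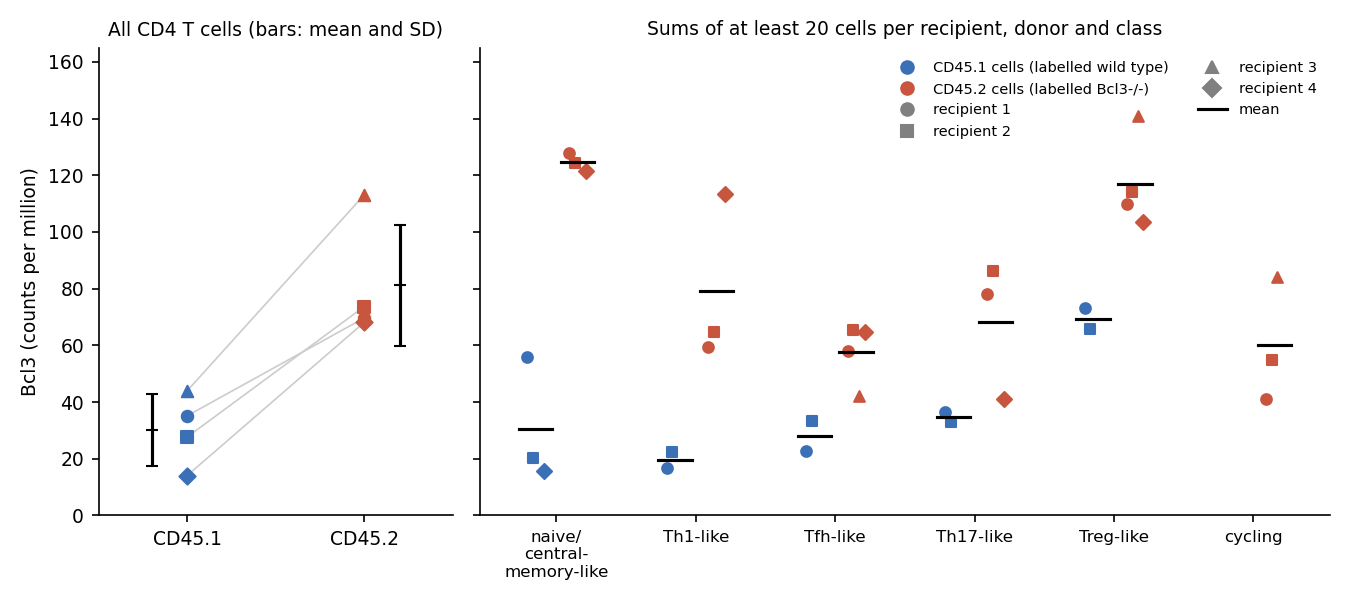
Bcl3 level in CPM by donor, for all CD4 T cells of each recipient with mean and SD (left). The right panel shows sums of at least 20 cells per recipient, donor and class. There each donor's sums were normalized apart, so the panel compares classes within a donor and not the donors. In all CD4 T cells the CD45.2 sums lie between 68.1 and 113 CPM and the CD45.1 sums between 14.1 and 43.9 CPM.

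Where Bcl3 is expressed was asked within each donor across classes, with Bcl3 left out of the clustering. Each donor's class sums were normalized apart here, so these CPM differ from those of the class comparisons below and do not compare donors. Among cells labelled wild type, regulatory T cell (Treg)-like cells had the highest mean, 69.3 ± 5.26 CPM (SD, n = 2), and Th1-like cells the lowest, 19.6 ± 3.91 CPM (n = 2). Th17-like cells lay at 34.6 ± 2.39 CPM (n = 2), naive/central-memory-like cells at 30.6 ± 22.1 CPM (n = 3) and Tfh-like cells at 27.9 ± 7.56 CPM (n = 2). Among cells labelled Bcl3-/-, naive/central-memory-like cells had 125 ± 3.17 CPM (n = 3) and Treg-like cells 117 ± 16.5 CPM (n = 4), against 79.2 ± 29.8 CPM in Th1-like (n = 3), 68.4 ± 24.1 CPM in Th17-like (n = 3), 60.0 ± 22.0 CPM in cycling (n = 3) and 57.6 ± 10.9 CPM in Tfh-like cells (n = 4). The cycling value of recipient 3, 84.1 CPM, came from mixed-profile barcodes alone. Classes differed in both donors (edgeR quasi-likelihood test over classes, adjusted p = 0.0049 for CD45.1 and 3.0e-07 for CD45.2). With DESeq2 this test over all classes was not called in CD45.1 cells (adjusted p = 0.121). Against Th1-like cells, the CD45.1 Treg-like cells were higher by a log2 difference of 1.77 (SE 0.36, adjusted p = 0.0012) and the CD45.2 Treg-like cells by 0.80 (SE 0.15, adjusted p = 2.2e-04). Naive/central-memory-like cells also lay above Th1-like cells, by 1.01 (SE 0.32, adjusted p = 0.033) among CD45.1 and 0.98 (SE 0.17, adjusted p = 1.0e-04) among CD45.2 cells. Among CD45.1 cells recipient 1 alone carried this difference, at 55.9 against 16.8 CPM. Recipient 2 had 20.3 against 22.3 CPM and the naive/central-memory-like cells of recipient 4 had 15.5 CPM.

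How the 2 donors contributed to the compartment was read from the tags. Cells labelled Bcl3-/- made up 91.0% (95% interval 90.4 to 91.6), 89.2% (88.6 to 89.9), 99.2% (98.8 to 99.4) and 92.7% (91.2 to 94.0) of the CD4 T cells with a donor in recipients 1 to 4, a mean of 93.0% ± 4.34 (SD, n = 4) from an inoculum of 50%. There were 10.1, 8.28, 119 and 12.7 CD45.2 cells per CD45.1 cell. The mean log2 odds were 4.24 ± 1.79 (SD), above 0 in 4 of 4 recipients (exact two-sided sign-flip permutation test, at the smallest p that 4 recipients allow, 2 of 16 sign patterns, which cannot go under 0.05). CD45.1 cells numbered 817, 978, 30 and 102, and recipient 3 stood apart. Without its mixed-profile barcodes, described next, recipient 3 had 93.4% CD45.2 cells and the mean log2 odds were 3.47.

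Recipient 3 differed from the other libraries in what its barcodes held. Of its barcodes, 3157 fell into groups of mixed profile in which Igkc, an immunoglobulin light chain made by B lineage cells, was widespread, and all of those with a donor call, 3151, were called CD45.2. With each barcode thinned to 3000 UMIs, 99.4% of them held Il17a, 84.4% Il22, 65.2% Ifng, 85.0% Ccl5, 79.4% Gzmb and 79.2% Igkc. Unthinned, the shares were 99.8%, 97.6%, 90.0%, 96.7%, 96.1% and 94.5%, at a median of 8963 UMIs. The other barcodes of recipients 1 to 4 held Il17a in 40.7%, 37.9%, 52.3% and 15% and Igkc in 1.06%, 8.31%, 10.6% and 1.25% after thinning, which left out 780, 655, 127 and 198 shallower barcodes there and 117 of the mixed profile. Most of recipient 3 (94.5% of its classified cells) therefore lay in unnamed clusters. These barcodes are part of the comparisons of all CD4 T cells and of class shares unless stated. The class-matched comparison holds none of them.

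**Figure D2:**
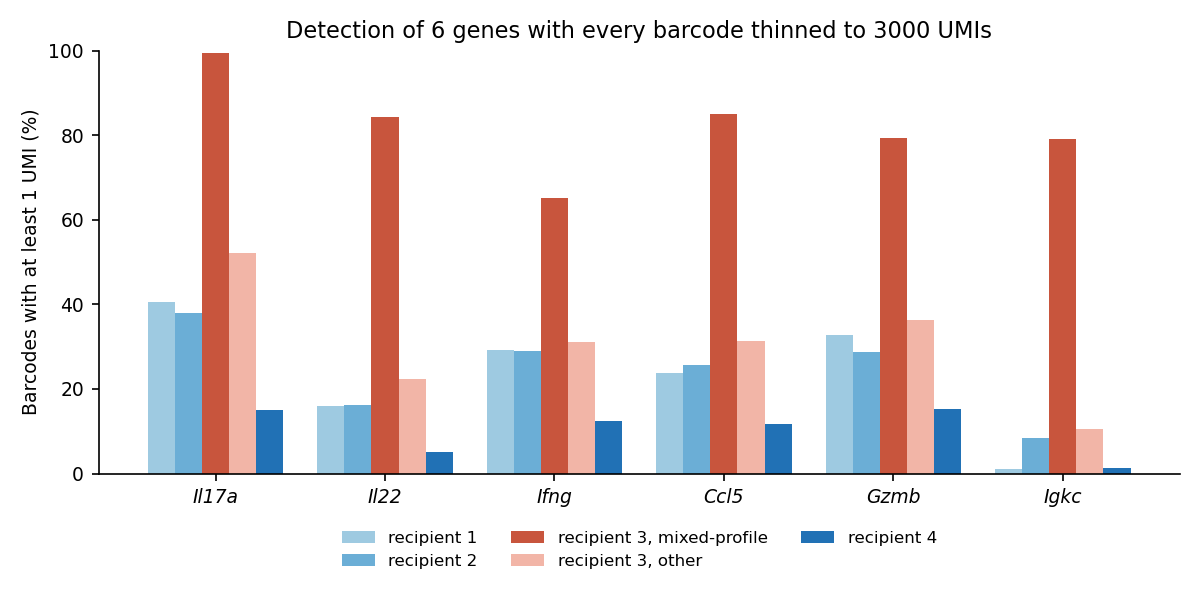
Share of barcodes (%) with at least 1 UMI of 6 genes after thinning to 3000 UMIs, for the mixed-profile barcodes of recipient 3 and all other barcodes of each recipient. Igkc was found in 79.2% of the mixed-profile barcodes and in at most 10.6% of the barcodes of any other group.

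Whether the donors differed in T cell classes was asked with the share of each class among a donor's cells. Naive/central-memory-like cells, marked by Ccr7, Lef1 and S1pr1, made up 23.7% ± 10.6 of CD45.1 cells and 4.04% ± 2.89 of CD45.2 cells (SD, n = 4), a log2 ratio of -2.57 (SE 0.47, edgeR adjusted p = 1.4e-04, lower in CD45.2 in 4 of 4 recipients). Th1-like cells, led by Ccl5, Xcl1 and Il12rb2, fell from 19.6% ± 12.5 to 4.54% ± 3.94, a log2 ratio of -2.18 (SE 0.48, adjusted p = 6.5e-04, 4 of 4). Th17-like cells, led by Il17f and Il17a and also high in Gzma, rose from 3.09% ± 3.61 to 11.9% ± 8.41, a log2 ratio of 1.80 (SE 0.52, adjusted p = 0.0059, observed share higher in 4 of 4). Treg-like cells, marked by Foxp3, rose from 6.05% ± 0.795 to 15.6% ± 9.18, a log2 ratio of 1.56 (SE 0.50, adjusted p = 0.0086, 3 of 4). Tfh-like cells (9.65% ± 2.65 and 9.54% ± 6.68, adjusted p = 0.94) and cycling cells (0.746% ± 1.06 and 1.40% ± 0.561, adjusted p = 0.94) did not pass the test. No CD45.1 cell of recipients 3 and 4 was Th17-like, 0 of 30 and 0 of 102 cells, which allows up to 10% and 2.94%. Unnamed clusters held 13.3%, 29.0%, 70.0% and 36.3% of the CD45.1 and 34.5%, 42.5%, 94.7% and 40.3% of the CD45.2 cells in recipients 1 to 4.

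In the exact two-sided sign-flip permutation test of the paired log2 odds, naive/central-memory-like and Th1-like cells reached the smallest possible p, 2 of 16 sign patterns, and Treg-like cells had p = 0.5. For Th17-like cells this test is not used, since the sign of recipient 3 was set by the 0.5 added to 0 of 30 cells. With clusters made without the genes called in the class-matched comparison, the 4 log2 ratios were -2.36, -2.01, 1.25 and 1.58. All stayed called (edgeR adjusted p = 1.3e-06, 1.5e-05, 0.0045 and 4.1e-04). That comparison had equalised the same classes, so genes that mark a class could largely escape the removal. This setting is therefore a weak check of the class shares. Without the mixed-profile barcodes the 4 log2 ratios were -2.40, -2.07, 1.77 and 1.68, and Treg-like cells were then higher in CD45.2 in 4 of 4 recipients. The Treg-like call was lost with unnamed clusters kept apart (log2 ratio 1.40, adjusted p = 0.126) and the Th17-like call with TMM on cell numbers (2.06, adjusted p = 0.069). Without the recipient block none of the 4 passed (adjusted p = 0.084, 0.10, 0.23 and 0.30), and without recipient 1 none did either; 1 passed without recipient 2 and 2 without recipient 4. Without removal of recipient means the log2 ratio of Th17-like cells was 0.58 (adjusted p = 0.629) and that of Treg-like cells 1.53 (adjusted p = 0.106).

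**Figure D3:**
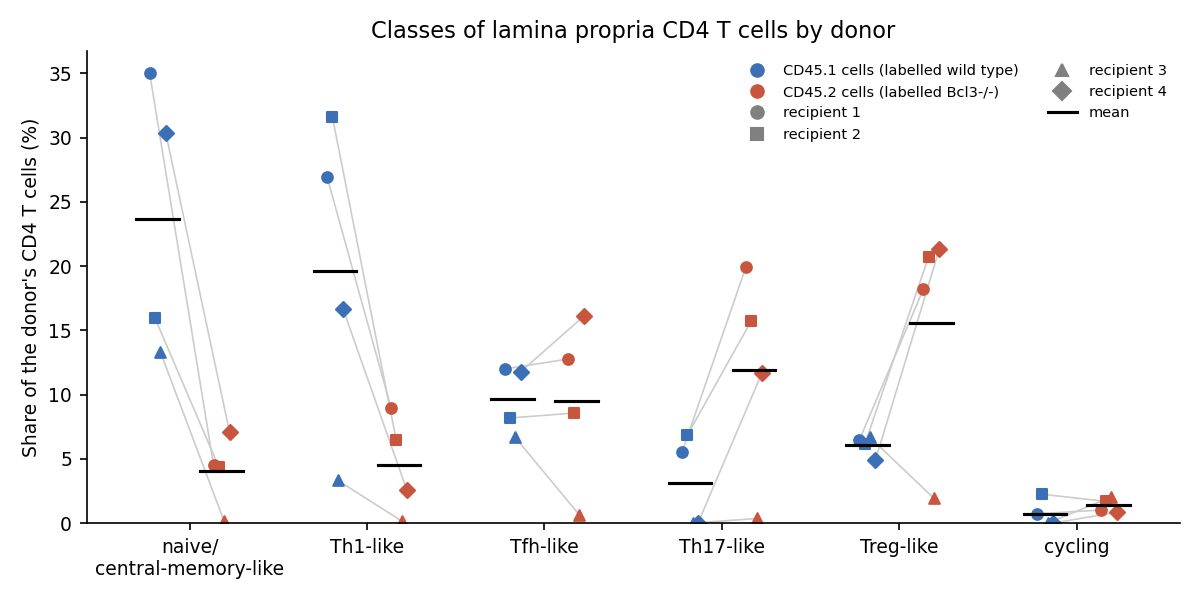
Share (%) of each class among a donor's CD4 T cells, with a point per recipient and donor, lines joining the donors of a recipient and bars at the means. Naive/central-memory-like cells lie higher in CD45.1 cells in every recipient, with means of 23.7% and 4.04%.

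The donors' transcriptomes were compared first over all CD4 T cells. Of 10780 genes tested, 273 were higher and 183 lower in the cells labelled Bcl3-/- (edgeR, 1583 genes at an unadjusted p under 0.05; DESeq2 called 209 and 151). Among genes with an average log2 CPM of at least 3 and the same direction in every recipient, immunoglobulin genes and Jchain apart, the largest rises were in Cxcl3, a neutrophil-attracting chemokine (log2 fold change 3.14, SE 0.30), Tff1 (4.05 ± 6.41 and 9.75 ± 6.23 CPM), Il22, a cytokine that acts on epithelium (2.49, SE 0.53; 110 ± 148 and 515 ± 295 CPM), Cd83 (2.27, SE 0.28; 33.1 ± 19.7 and 177 ± 72.3 CPM), Ildr1 (2.19, SE 0.26), Marcks (2.08, SE 0.18), the costimulatory ligand Cd86 (2.04, SE 0.25) and Krt18 (1.84, SE 0.24), all in 4 of 4 recipients with adjusted p of at most 0.02. Among the largest falls were Ctse, a protease gene that lies within 10 Mb of Ptprc (-3.94, SE 0.18; 66.4 ± 13.7 and 5.07 ± 2.13 CPM), Igfbp4 (-3.90, SE 0.30), Gzmk (-3.06, SE 0.36), Ifi208 (-2.21, SE 0.20), S1pr1, which guides exit from tissue (-2.10, SE 0.22), Lef1 (-2.06, SE 0.21) and Cmah (-1.87, SE 0.27). Each fell in 4 of 4 recipients with an adjusted p of at most 0.002.

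Among the gene lists, 9 of 12 tested naive and central memory genes fell and 0 rose (11 fell when adjusted over the list alone), a list change in camera with adjusted p = 1.7e-14. The effector Treg and suppression list had 6 of 18 genes up and 0 down (13 up adjusted over the list alone, camera adjusted p = 2.4e-06), among them Ebi3 (log2 fold change 2.32, SE 0.30), Il10 (1.84, SE 0.29), which lies within 10 Mb of Ptprc, and Entpd1 (0.89, SE 0.15). Treg identity had 5 of 14 up and 0 down (5 adjusted over the list alone, camera adjusted p = 7.2e-05), led by the lineage factor Foxp3 (1.56, SE 0.21; 25.8 ± 7.70 and 90.6 ± 18.3 CPM), Capg (1.33) and Ctla4 (1.11). In the Th17 programme 8 of 19 rose and 1 fell (14 and 2 adjusted over the list alone, camera adjusted p = 5.6e-05), with Il17f (1.84, SE 0.29) and Il1r1 (1.19, SE 0.16) among them. These 4 calls had adjusted p = 0.225 with an estimated correlation. Proliferation genes were called upward without a single called member, 0 of 18 up and 0 down, also when adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.656 with an estimated correlation). The lymphotoxin, TNF ligand and receptor list had 1 of 14 up, Tnf (0.66, SE 0.14), and 4 up adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.656 with an estimated correlation). This call was also lost with fry and without recipient 1, 2 or 3. With fry, the naive, Th17 and both Treg lists kept an adjusted p under 0.05, at 0.0223 for the first and 0.0475 for the others, and so did those of plasma cells (0.0282), B cells (0.0475) and, downward, the BCL2 family (0.0475).

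The remaining lists of T cell programmes and responses were not called by camera in all CD4 T cells. In the NF-kB family and feedback list, which holds the closest relatives of the targeted gene, 2 of 20 genes rose and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.449). The Th1 and cytotoxic programme had 1 of 20 up and 4 down (2 and 6 adjusted over the list alone, 0.244), among the latter Eomes (-3.97, SE 0.39) and Prf1 (-1.48, SE 0.20). Of the BCL2 family and death receptors 2 of 16 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.368). Bcl2, which protects T cells from death, fell from 305 ± 39.3 to 96.3 ± 9.70 CPM (log2 fold change -1.66, SE 0.17, adjusted p = 3.7e-04, 4 of 4 recipients), while Bcl2l1 (1.12, SE 0.21) and Pmaip1 (0.62, SE 0.14) rose. Coinhibitory receptors had 4 of 9 up and 2 down (6 and 3 adjusted over the list alone, 0.244), with Cd160 at -1.13. The Th2 programme had 2 of 8 up and 0 down (4 and 1 adjusted over the list alone, 0.419), namely Ccr4 (1.00) and Il9r (1.21). The Tfh programme had 1 of 11 up and 2 down (2 and 2 adjusted over the list alone, 0.791), with Pdcd1 (0.76), Il6ra (-1.38) and Btla (-0.71). Gut homing and tissue residence had 1 of 15 up and 1 down (2 and 3 adjusted over the list alone, 0.574), Ccr2 (0.87) and Itga1 (-1.06). IL-2 and STAT5 targets had 1 of 13 up and 1 down (2 and 2 adjusted over the list alone, 0.79), Socs2 (0.88) and Bcl2, with a median log2 fold change of 0.07, a mean of -0.06 and a test direction of down. Of 15 interferon gamma response genes 1 rose, Gbp6 (0.79), and 0 fell (1 and 0 adjusted over the list alone, 0.244). Of 19 dissociation and stress genes 1 fell, Hspa1a (-1.06), and 0 rose, also adjusted over the list alone (0.362). Type I interferon response (0 of 15; 0.927), T cell receptor activation response (0 of 18; 0.332) and glycolysis (0 of 16; 0.244) had 0 genes called in edgeR, against 1 fall, 0 and 0 when adjusted over the list alone.

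Markers of other cell types moved with the donor as well. Plasma cell genes rose as a list, with 2 of 6 up and 0 down (3 up adjusted over the list alone, camera adjusted p = 0.027; adjusted p = 0.321 with an estimated correlation), namely Jchain (2.88, SE 0.26) and Igha (3.76, SE 0.42). Igkc rose by 3.78 (SE 0.43; 16.3 ± 17.5 and 280 ± 327 CPM), 1 of 5 tested B cell genes (2 adjusted over the list alone, camera adjusted p = 0.249). In recipients 1 and 2 the Igkc UMIs of CD45.2 cells lay mostly in 3 and 11 cells with at least 50 Igkc UMIs (93.0% and 86.6%), while in recipient 3 86.2% of CD45.2 and 13.3% of CD45.1 cells held Igkc. Myeloid genes (0 of 5 called, 1 adjusted over the list alone, 0.116) and gamma-delta T cell genes (1 of 7 up, Tcrg-V4 at 1.17, and 1 down, Tcrg-C4 at -1.56; 2 and 2 adjusted over the list alone, 0.791) were not called as lists. Too few members were tested for the lists of mast cells, epithelium, stroma, CD8 T cells, innate lymphoid cells and erythrocytes, of which Kit (1.65), Krt18 and Klrd1 (-2.68) were called. Of the sex-linked genes Xist (0.05, adjusted p = 0.943) and Tsix (0.01) did not differ detectably between the donors.

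The number of called genes depended on the libraries. Without recipient 3 it was 1307 and included all 456, without the mixed-profile barcodes 1379, of which 449 were shared, and without recipients 1 or 2 it fell to 134 or 130. Without the block 112 genes were called, all among the 456.

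To reduce the part of class mix in these changes, the donors were compared with equal cells per recipient and class. Cells were matched by class and, among unnamed cells, by cluster. A different mix of clusters therefore remains within naive/central-memory-like and Treg-like cells, which hold several clusters each. No mixed-profile barcode entered, since recipient 3 had 0 CD45.1 cells in clusters 3, 7 and 13. Of 9613 genes, 169 were higher and 208 lower in the cells labelled Bcl3-/- (edgeR, 1239 at an unadjusted p under 0.05; DESeq2 45 and 109), and 154 were called in both this and the unmatched comparison. Bcl3 stayed higher (log2 fold change 1.37, SE 0.12, adjusted p = 1.9e-08). Under the same limits, which hold for each class as well, the other largest rises were Ube2t (1.36), which lies within 10 Mb of Ptprc, AA467197 (1.36), Iltifb (1.23), a close copy of Il22 with which it may share reads, Cd86 (1.22, SE 0.20), Gpr55 (1.12, SE 0.12), Trio (1.05) and Rell1 (1.05). Among the largest falls were Ctse (68.1 ± 14.1 and 5.74 ± 2.67 CPM), Rab4a (-1.38), Ramp1, a subunit of the receptor for the neuropeptide CGRP (-1.34, SE 0.11; 78.7 ± 10.4 and 32.9 ± 3.99 CPM), Igfbp4 (-1.19), St8sia6 (-1.12), Car2 (-1.10) and Qpct (-1.08). Il10 (-0.06) and Itga1 (0.04), called in the unmatched comparison, had the opposite sign here and were not called.

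Of the lists, 8 of 12 naive and central memory genes still fell and 0 rose (9 adjusted over the list alone, camera adjusted p = 3.8e-07), among them Lef1 (-1.07, SE 0.08) and Ccr7 (-0.82, SE 0.09). In the Th17 programme 7 of 19 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.015), with Ccr6 (0.87, SE 0.12) and Maf (0.36, SE 0.06). Effector Treg and suppression genes had 3 of 16 up and 0 down (5 and 1 adjusted over the list alone, 0.020). T cell receptor activation genes had 0 of 18 up and 1 down, Egr3 (-1.24, SE 0.23), with 1 and 4 adjusted over the list alone (0.0089), and dissociation and stress genes 0 of 19 up and 2 down, Hspa8 (-0.24) and Hspa1a (-0.89), with 2 and 9 adjusted over the list alone (0.021). With an estimated correlation the adjusted p was 0.424 for the first 3 of these lists and 0.623 for the last 2. Called in all CD4 T cells but not here were Treg identity (1 of 12 up, 3 adjusted over the list alone, camera adjusted p = 0.265), the lymphotoxin, TNF ligand and receptor list (2 of 14 up and 1 down, 3 and 1 adjusted over the list alone, 0.718) and proliferation (0 of 13, also adjusted over the list alone, 0.921). Within the NF-kB list, not called as a whole (3 of 20 up, 1 down, 3 and 1 adjusted over the list alone; 0.408), Nfkbid, which encodes another atypical IkB protein and lies on chromosome 7 from 30421732, outside 10 Mb but within 20 Mb of Bcl3, fell from 58.6 ± 13.7 to 21.5 ± 10.8 CPM (log2 fold change -1.05, SE 0.12, adjusted p = 6.8e-06, 4 of 4 recipients), while Cd83 (1.04, SE 0.13) and Tnip1 (0.32, SE 0.09) rose. Flanking DNA of another strain is possible at Nfkbid. Bcl2 fell from 312 ± 40.0 to 155 ± 35.4 CPM (-0.90, SE 0.08, adjusted p = 1.5e-08). Igkc rose by 4.18 (SE 0.28) and Jchain by 3.37. Before matching, 3 and 11 CD45.2 cells of recipients 1 and 2 held 93.0% and 86.6% of that donor's Igkc UMIs. How many of them entered the matched set was not examined, so the rise may rest on few cells. DESeq2 called 154 genes, of which 152 were shared; without recipients 1 or 2 the count was 47 or 134, and without the block 9.

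Naive/central-memory-like cells were compared in recipients 1, 2 and 4 (473 CD45.1 and 819 CD45.2 cells). Of 8250 genes 267 were higher and 218 lower in the cells labelled Bcl3-/- (edgeR, 1360 at an unadjusted p under 0.05; DESeq2 73 and 100). Bcl3 was 27.7 ± 20.2 and 110 ± 2.44 CPM (log2 fold change 1.64, SE 0.22, adjusted p = 5.4e-04, 3 of 3 recipients). Stmn2 had 2 UMIs in the 473 CD45.1 and 82 in the 819 CD45.2 cells. The other largest rises were Cd83 (2.77, SE 0.33), Capn3 (2.69), Klk1b27 (2.51) and Cpe (2.38, SE 0.29). Ctse (-4.01, SE 0.23), Cldn10 (-2.49), Tnfrsf9 (-2.04) and Atp1b1 (-1.83) were among the largest falls. Naive and central memory genes had 1 of 12 up and 8 down (1 and 10 adjusted over the list alone, camera adjusted p = 2.7e-06), with Lef1 at -1.37 (SE 0.12) and Satb1 at -0.80 (SE 0.09). Th17 programme genes had 13 of 17 up and 1 down (14 and 2 adjusted over the list alone, 2.3e-05), with Maf at 1.37 (SE 0.12) and Ramp1 at -1.25 (SE 0.12). Gut homing and residence genes had 7 of 14 up and 0 down (8 adjusted over the list alone, 0.0010), with Rgs1, within 10 Mb of Ptprc, at 1.15 (SE 0.08) and P2rx7 at 1.07. Th2 genes had 3 of 5 up (5 adjusted over the list alone, 2.6e-05), with Ccr4 at 29.0 ± 24.1 and 60.4 ± 22.6 CPM, and Treg identity genes 3 of 12 up and 1 down (6 and 1 adjusted over the list alone, 0.0078), with Capg at 1.00. Type I interferon genes had 4 of 14 up (5 adjusted over the list alone, 0.0010), with Ifit3 at 1.58 and Isg20 at 1.12, and interferon gamma genes 4 of 15 up (6 adjusted over the list alone, 0.0022). With an estimated correlation the adjusted p of these 7 lists was 0.434 to 0.480. Bcl2 (-1.09, SE 0.09) and Nfkbid (-1.04, SE 0.22) fell. Igkc, at 13.1 ± 12.9 and 391 ± 670 CPM (4.98, SE 0.41), was higher in CD45.2 in 1 of 3 recipients.

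The donors differed in how this class was spread over its 2 clusters, and in recipient 1 different clusters held most of it. In that recipient, 235 of the CD45.1 cells lay in cluster 12, led by Igfbp4 and Lef1, and 51 in cluster 11, led by S1pr1 and Klf2, whereas 128 and 246 CD45.2 cells did. In recipient 2 the numbers were 75 and 81 against 34 and 319, and in recipient 4 12 and 19 against 4 and 88, so that cluster 11 held most of the class in both donors there. With equal cells of each cluster, 8 of 31 named genes kept their call, among them Cd83, Cpe, Ctse, Maf, Ramp1 and Bcl2. The call was lost for 23, among them Lef1, Satb1, Rgs1, P2rx7, Ccr4, Capg, Ifit3, Isg20, Nfkbid and Atp1b1. In that setting 29 genes were called. The count was 9 without the block and 194 without recipient 1.

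Th1-like cells were compared in recipients 1 and 2 (529 CD45.1 and 1263 CD45.2 cells). Of 9392 genes 261 were higher and 308 lower in the cells labelled Bcl3-/- (edgeR, 1370 at an unadjusted p under 0.05; DESeq2 29 and 55). Bcl3 was 19.5 ± 3.95 and 60.0 ± 3.61 CPM (log2 fold change 1.61, SE 0.18, adjusted p = 3.4e-09, n = 2). Cytotoxic genes moved in both directions. Gzma (2.32, SE 0.21), Gzmb (1.55, SE 0.05; 488 ± 90.3 and 1422 ± 208 CPM) and the interleukin 12 receptor chain Il12rb2 (1.72, SE 0.09) rose, while Gzmk (-2.11, SE 0.15) and Eomes, a factor of memory and cytotoxic T cells (-3.32, SE 0.25), fell. Olfm1 had 3 UMIs in the 529 CD45.1 and 97 in the 1263 CD45.2 cells. Cd8a (2.41), Ube2t (2.09) and Marcks (2.04) were the other largest rises, and Ctse (-3.47), Esm1 (-2.39) and Rflnb (-1.92) the other largest falls. The Th1 and cytotoxic programme had 7 of 20 up and 5 down (8 and 5 adjusted over the list alone, camera adjusted p = 0.571). Only the Tfh programme was called as a list, with 1 of 9 up and 3 down (1 and 6 adjusted over the list alone, camera adjusted p = 0.021; adjusted p = 0.816 with an estimated correlation), including Izumo1r (-1.04) and Slamf6 (-0.74). Of the gut homing genes 7 of 15 rose and 1 fell, Itga4, the alpha4 integrin chain (-1.37, SE 0.09), with 7 and 2 adjusted over the list alone, and 8 of 19 dissociation and stress genes fell and 1 rose, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.123 for both lists). Bcl2 (-0.57, SE 0.07) and Ltb (-0.61, SE 0.07) fell. Igkc (1.20, SE 0.24) rose in 1 of 2 recipients. DESeq2 called 84 genes, all among the 569, and no filter, no block, stricter cells and sums of at least 10 cells gave 121, 108, 281 and 301.

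Treg-like cells were compared in the same 2 recipients (113 CD45.1 and 3182 CD45.2 cells), and 8 of 10442 genes were higher and 8 lower in the cells labelled Bcl3-/- (edgeR, 623 at an unadjusted p under 0.05; DESeq2 1 and 6). Bcl3 itself, at 72.8 ± 5.59 and 116 ± 3.57 CPM, did not pass the test (log2 fold change 0.67, SE 0.19, adjusted p = 0.46, n = 2). Cd86 (1.60, SE 0.27), the interferon-induced chemokine Cxcl10 (1.59, SE 0.19), Dock10 (0.75), Jun (0.54) and Rgs1 (0.48) rose. Ramp1 (-2.12, SE 0.29), Ccl20, the ligand of CCR6 (-1.63, SE 0.15; 294 ± 78.3 and 94.5 ± 11.4 CPM), Nfkbid (-1.56, SE 0.21; 96.6 ± 16.4 and 32.7 ± 1.72 CPM), Zeb2 (-1.29), Oser1 (-1.24), Il1rl1 (-2.93, SE 0.47) and Izumo1r (-0.93) fell. No list was called by camera (lowest adjusted p = 0.052, for gamma-delta T cell genes), 0 of 14 Treg identity and 0 of 18 effector Treg genes passed over all genes, and 1 rose and 4 fell, and 0 rose and 1 fell, when adjusted over the list alone. Igkc (3.56, SE 0.36) and Igha (3.13, SE 0.40) were also higher. Over all classes, 3 and 11 cells held 93.0% and 86.6% of the Igkc UMIs of CD45.2 cells in recipients 1 and 2. How many of them were Treg-like was not examined. The donors were spread differently over the 2 clusters of this class, with 26 and 27 CD45.1 cells against 1085 and 417 CD45.2 cells in clusters 2 and 8 of recipient 1, and 25 and 35 against 953 and 727 in recipient 2. Markers of cluster 8 include Izumo1r, and no comparison within clusters was made. The count was 134 with the fixed ratio donor call, 88 with the stricter cell filter, 40 with equal cells, 67 with no filter and 3 without the block.

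Th17-like cells were compared in recipients 1 and 2 as well (112 CD45.1 and 2918 CD45.2 cells), and 23 of 10079 genes were higher and 22 lower (edgeR, 630 at an unadjusted p under 0.05; DESeq2 2 and 5). Bcl3 was 37.3 ± 2.11 and 86.0 ± 6.43 CPM (log2 fold change 1.22, SE 0.26, adjusted p = 0.0019, n = 2). Il22 (1.49, SE 0.14; 672 ± 690 and 1608 ± 224 CPM), Il17f (0.99, SE 0.14), Cd83 (1.37, SE 0.25), Serpine2 (2.68, SE 0.48), Cxcl3 (2.21, SE 0.53), Pim2 (1.67) and Iltifb (1.62) rose, and Xlr had 0 UMIs in CD45.1 and 205 in CD45.2 cells. The Xlr counts are raw totals over 112 and 2918 cells, so far fewer UMIs are due on the CD45.1 side at equal levels. The CD45.1 levels of Il22 lay far apart in the 2 recipients, so the size of its rise differed between them. Bcl2 fell from 99.2 ± 30.6 to 22.0 ± 7.88 CPM (-2.17, SE 0.25, adjusted p = 5.0e-15), and Ramp1 (-2.18, SE 0.34), Bcl2a1a (-1.76), which has near-identical copies, Myo1e (-1.38), Cxcr4 (-1.31), within 10 Mb of Ptprc, Areg (-1.24, SE 0.13), Nfkbid (-1.08, SE 0.23) and Il2ra (-0.91, SE 0.22) fell as well. No list was called by camera (lowest adjusted p = 0.291). The Th17 programme had 2 of 18 up and 1 down (2 and 2 adjusted over the list alone, camera adjusted p = 0.964). The immunoglobulin heavy chain Ighm fell by 3.03 on the log2 scale. Without the block 1 gene was called, with equal cells 28 and with the stricter cell filter 21.

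Tfh-like cells were likewise compared in recipients 1 and 2 (178 CD45.1 and 1748 CD45.2 cells), and 56 of 9373 genes were higher and 61 lower (edgeR, 789 at an unadjusted p under 0.05; DESeq2 4 and 3). Bcl3 was 28.5 ± 7.90 and 61.8 ± 5.27 CPM (log2 fold change 1.14, SE 0.25, adjusted p = 0.0012, n = 2). The chemokines Ccl1 and Xcl1 had 1 and 2 UMIs in CD45.1 and 215 and 204 in CD45.2 cells. Krt18 had 2 and 163, and Fbxo17, within 10 Mb of Bcl3, 2 and 144. These are raw totals over 178 and 1748 cells, so far fewer UMIs are due on the CD45.1 side at equal levels. Il2 (2.39, SE 0.49), Il22 (2.20, SE 0.19) and Cd83 (1.14, SE 0.13) rose, and Ctse (-4.12, SE 0.27), Ctsw (-1.61), Ramp1 (-1.48, SE 0.21), Ifng (-1.35, SE 0.21), Cdk5rap1 (-1.22) and Nfkbid (-1.17, SE 0.22) fell. Th2 genes were called upward with 0 of 5 members called (2 adjusted over the list alone, camera adjusted p = 0.043), and naive and central memory genes downward with 3 of 9, among them Ccr7 (-0.82) and Klf2 (-0.78) (5 adjusted over the list alone, 0.043); both had adjusted p = 0.885 with an estimated correlation. The Tfh programme had 0 of 12 called, also adjusted over the list alone (0.668). Igkc rose by 5.83 (SE 0.31). Over all classes, 3 and 11 cells held 93.0% and 86.6% of the Igkc UMIs of CD45.2 cells in recipients 1 and 2. How many of them were Tfh-like was not examined. Under the fixed ratio donor call Ifng was 0.64 (adjusted p = 0.724), and with the stricter cell filter Ccl1 was -0.68 (adjusted p = 0.445) and Xcl1 -1.51 (adjusted p = 3.7e-06), so the direction of these 3 genes was not stable. The count was 74 with the fixed ratio call, 44 with equal cells, 60 with sums of at least 10 cells and 4 without the block.

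Whether the donor effect itself differed between classes was tested with interaction terms in recipients 1 and 2. Between Treg-like and Th17-like cells 7 of 10844 genes differed (edgeR, 444 at an unadjusted p under 0.05; DESeq2 2): the effect on Ccl20 was lower in Treg-like cells by 1.68 (interaction -1.68, SE 0.23, adjusted p = 1.5e-05), as were those on Il22 (-2.37, SE 0.50), Zeb2 (-1.29) and Nkg7 (-1.28), while Ssh2 (1.22), Igkc (4.48) and Ighm (2.81) were higher. Between Treg-like and Th1-like cells 32 of 9976 differed (759; DESeq2 18), with Gzmb (-1.82, SE 0.13), Ccl20 (-2.92, SE 0.35), Ikzf2 (-0.96), Maf (-0.64) and Ccr9 (-0.90) lower and Itga4 (1.04, SE 0.13) and Klf2 (1.14) higher in Treg-like cells. Between Th17-like and Th1-like cells 68 of 9955 differed (752; DESeq2 17), with Bcl2 (-1.59, SE 0.22), Il12rb2 (-1.73) and Il18r1 (-1.08) lower and Itga4 (1.08, SE 0.16) higher in Th17-like cells. For Bcl3 the differences of -0.57 (SE 0.34), -0.94 (SE 0.28) and -0.38 (SE 0.35) did not pass (adjusted p = 1, 0.241 and 0.921). Apart from list members, the genes of this paragraph were chosen after their values were seen.

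Because the CD45.1 allele of Ptprc and a targeted Bcl3 locus can each carry flanking DNA of another strain, called genes were counted around both. Within 10 Mb of Ptprc (chromosome 1 from 138062861 to 138175708, minus strand) 7 of 69 tested genes were called, 10.1% against 4.19% elsewhere (odds ratio 2.58, 95% interval 0.991 to 5.69, two-sided Fisher's exact p = 0.026). They were Ctse (chromosome 1 from 131638306 to 131675505), Lrrn2 (1.55), Rnpep (1.18), Il10, Phlda3 (1.62), Ikbke (-0.65) and Cd55 (-0.80). In class-matched cells 10 of 62 were called (16.1% against 3.85%, odds ratio 4.81, 2.16 to 9.66, Fisher's exact p = 1.3e-04), and within 5 Mb the odds ratio was 1.33 in the unmatched (Fisher's exact p = 0.664) and 4.58 in the class-matched comparison (Fisher's exact p = 0.0076). Around Bcl3, 6 of 178 genes were called (odds ratio 0.79, 0.284 to 1.77, Fisher's exact p = 0.708), among them Ppm1n (2.27), Zfp30 (2.79), Fbxo17 (1.17), Lig1 (0.64) and Erf (-0.86), and in class-matched cells 11 of 152 (odds ratio 1.94, Fisher's exact p = 0.052). Within 20 Mb of Bcl3, 17 of 239 genes were called in class-matched cells (odds ratio 1.92, 1.09 to 3.19, Fisher's exact p = 0.017), and within 5 Mb 1 of 61 (odds ratio 0.41, Fisher's exact p = 0.734). Expression values of these genes may carry a strain difference that the design cannot part from the genotype.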

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

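Of the tests in this part, the one on T cell receptor beta genes and the counts of called genes after donors were swapped in some recipients were written before their values were seen, the interaction tests between classes were planned, and all others were chosen only after the result was seen.

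In 59 groups of 4 recipients, 5 had a single recipient far from the other 3, with a gap to its nearest neighbour above the limit that Dixon's test sets for 4 values, and chance gives this in about 1 in 20 groups. In recipient 3 the median depth was 8584 UMIs per barcode, against 5439 to 5790 in the others. Treg-like cells made up 1.93% of CD45.2 cells in recipient 3, against 18.2% to 21.3%, and 1.96% of all its cells, against 17.2% to 20.1%. Without the mixed-profile barcodes they made up 16.3% of its CD45.2 cells. Bcl3 in CD45.2 cells lay at 113 CPM in recipient 3, against 68.1 to 73.7 CPM. Il22 in CD45.1 cells lay at 331 CPM in recipient 2, against 16.9 to 47.1 CPM.

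The donor effect differed between classes by an interaction test for 7 genes between Treg-like and Th17-like cells, 32 between Treg-like and Th1-like cells, and 68 between Th17-like and Th1-like cells.

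Bcl3 was higher in the cells labelled Bcl3-/- than in those labelled wild type. A different mix of classes, though not of clusters within them, was excluded as the whole reason, since the log2 difference in class-matched cells was 1.37, and cells of very high UMI counts were excluded as well, at 1.37 without them. Exchanged donor labels, or 3' reads that a targeted allele still makes, could each give the same counts, and the 410 Bcl3 UMIs of the CD45.1 cells cannot tell them apart. A rise of Bcl3 transcription in cells that lack the protein is the biological alternative, and no test of it was possible without the sequence of the allele.

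In recipient 3, barcodes held Il17a, Il22, Ifng, Ccl5, Gzmb and Igkc together. A common pool of free RNA in the droplets would spread these genes evenly. The median variance over mean of 5 T cell genes was 1.19 there (1.17 to 2.12 by gene), near the value of 1 for random counts. It was 36.5, 22.1 and 26.9 in recipients 1, 2 and 4, and 28.0 in the other barcodes of recipient 3. Those groups pool many clusters, whereas the mixed-profile barcodes were picked by cluster, so part of the gap may come from that choice. Igkc lay at 3.15, against 771, 569 and 2.02 in recipients 1, 2 and 4 and 3.30 in the other barcodes of recipient 3. A T cell state that makes these cytokines at once would keep a single T cell receptor beta chain per cell. Of the 3157 mixed-profile barcodes, 92 had at least 2 Trbv UMIs. Of these, 79 (85.9%) held 2 or more Trbv genes, against 22.1% to 32.2% elsewhere. This argues against such a state alone in those 92 barcodes. Free RNA or several cells in a droplet would also add Trbv genes, so the test does not exclude the state for the group. The median spread of the 5 T cell genes is what a pool of free RNA would give, while that of Igkc was wider. The CD45.2 call of these barcodes may follow the more frequent tag.

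Called genes were more frequent near Ptprc than elsewhere. A different mix of classes, though not of clusters within them, was excluded, since the odds ratio was 4.81 in class-matched cells. Flanking DNA of the strain that carries the CD45.1 allele would place called genes around Ptprc above other regions. In class-matched cells the share near Ptprc was 16.1%, against a median of 3.64% over 255 windows of 20 Mb. Of these windows 0.784% had a share as high. The windows overlapped, and those over Ptprc itself were not left out. That percentage therefore does not set Ptprc against separate regions, and flanking DNA stayed possible. No biological explanation was tested.

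With the donors swapped in some recipients, the splits are too few for a share under 0.05. The labels as given called 456 genes in all CD4 T cells and the highest other split 15, 1 of 8 splits reaching the real count. In class-matched cells the numbers were 377 and 134, 1 of 8, and in naive/central-memory-like cells 485 and 0, 1 of 4.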

How the results depend on the processing

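All tests in this part were planned except those under settings stated to be chosen after seeing the data. Depth limits the CD45.1 side, whose sums held few cells, and the comparisons in 2 recipients had the fewest residual degrees of freedom. Bcl3 by donor kept its direction and its call under every alternative, with 1.19 for equal cells and 1.24 to 1.60 with each recipient left out, and so did the sign of the donor share, from 3.35 to 4.63. Of the 49 genes named in all CD4 T cells, 49 kept their call with the fixed ratio donor call, the stricter filter, Scrublet calls kept and no filter, 44 with DESeq2 and 45 with equal cells. Without recipient 1 18 of them lost their call, without recipient 2 16 and without recipient 4 8, and in class-matched cells 29 of 45 kept it, 14 lost it and 2 turned direction. Where a result changed, the cause was not tested unless stated.

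The recipient block pairs the donors within an animal. Without it the counts of called genes were 112 in all CD4 T cells, 9 in class-matched, 9 in naive/central-memory-like, 108 in Th1-like, 3 in Treg-like, 1 in Th17-like and 4 in Tfh-like cells, and 1, 5 and 3 for the interactions of Treg-like with Th17-like, Treg-like with Th1-like and Th17-like with Th1-like cells. Of the 49 named genes, 20 kept their call and 29 lost it. The class shares called fell from 4 to 0, with log2 ratios of -2.58 (adjusted p = 0.084) for naive/central-memory-like, -2.17 (0.104) for Th1-like, 1.64 (0.231) for Th17-like, 1.37 (0.296) for Treg-like and -0.047, a reversed sign, for Tfh-like cells.

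With DESeq2 the counts were 173 in naive/central-memory-like, 84 in Th1-like, 7 in Treg-like, 7 in Th17-like, 7 in Tfh-like and 154 in class-matched cells, and 2, 18 and 17 for the 3 interactions. The adjusted p of Bcl3 by class in CD45.1 cells was 0.121. With no filter on low counts 765 genes were called in all CD4 T cells, 121 in Th1-like and 67 in Treg-like cells. Equal cells of both donors gave 307 in naive/central-memory-like, 40 in Treg-like, 28 in Th17-like and 44 in Tfh-like cells. The stricter cell filter gave 281 in Th1-like, 88 in Treg-like and 21 in Th17-like cells, and the fixed ratio donor call 134 in Treg-like and 74 in Tfh-like cells.

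With an estimated correlation 0 of 7 lists stayed called, and with each recipient left out 6 to 7 were called. Within 5 Mb of Ptprc the odds ratio was 1.33 (Fisher's exact p = 0.664). TMM on cell numbers gave 2.06 (adjusted p = 0.069) for Th17-like cells. Without removal of recipient means 2 class shares were called, with 0.58 (0.629) for Th17-like and 1.53 (0.106) for Treg-like cells.

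Chosen after seeing the data were all settings tried on the class-matched counts and on the Bcl3 level beyond DESeq2, the block and leaving out recipients, and also named classes only, which gave 1544 genes in all CD4 T cells, mixed-profile barcodes left out with 1379, cluster-matched cells with 29 in naive/central-memory-like cells, and sums of at least 10 cells with 301 in Th1-like and 60 in Tfh-like cells. Unnamed clusters kept apart gave 1.40 (edgeR adjusted p = 0.126) for the share of Treg-like and -0.13 for that of Tfh-like cells. Clusters made without the genes called in the class-matched comparison gave -0.014 for Tfh-like cells. Near Bcl3 the odds ratio turned to 1.94 (Fisher's exact p = 0.052) in class-matched cells.

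Named genes that turned direction were Il10 (-0.057, adjusted p = 0.934) and Itga1 (0.0413, 0.946) of all CD4 T cells in class-matched cells, and in Tfh-like cells Ifng with the fixed ratio call (0.64, 0.724) and Ccl1 (-0.68, 0.445) and Xcl1 (-1.51, 3.7e-06) with the stricter filter.

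With each recipient left out in turn, counts ranged from 130 to 1307 in all CD4 T cells, 47 to 460 in class-matched and 194 to 491 in naive/central-memory-like cells, and 0 to 4 class shares were called. Their log2 ratios ranged from -3.41 to -2.33 for naive/central-memory-like, -2.75 to -2.05 for Th1-like, 1.53 to 2.77 for Th17-like, 1.07 to 1.71 for Treg-like and -0.45 to 0.17 for Tfh-like cells. Leaving out a recipient was not run for classes compared in 2 recipients or for interactions, and gene lists were not tested across classes.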

Other observations

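No test of a hypothesis was added in this part, and all its values were chosen only after they were seen.

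Several unnamed clusters had clear leading genes. Cluster 1, of 2503 cells, was led by Apol7b, Lmo4, Tnfsf14 and Il7r, and cluster 4, of 2299 cells, by Pxdc1, Atf3, Hk2 and Cd40lg. Cluster 10, of 960 cells, was led by Nrgn, Penk, Kit and Il21 and carried the Th17 markers Il17a and Il22 beside Pdcd1, Tox2 and Krt18, so that it met more than 1 class. Cluster 9, of 1016 cells, had a median of 0.216 of its own library's UMIs. Cluster 14 held 20 of the 30 CD45.1 cells of recipient 3 and 285 of its CD45.2 cells.

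Immunoglobulin RNA was uneven among recipients. Igkc was found in 1.10% of CD45.1 and 1.96% of CD45.2 cells of recipient 1, in 13.3% and 14.4% of recipient 2, and in 1.96% and 1.47% of recipient 4. Il17a, Ifng and Ccl5 lay together in 55.7% of the mixed-profile barcodes of recipient 3 and in 3.12%, 3.95%, 7.86% and 0.916% of the other barcodes of recipients 1 to 4. The CD45.1 tag made up 11.7% of the 2 tags in the mixed-profile barcodes and 8.37%, 11.7%, 10.6% and 7.80% in the others.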
